A study of Rattus norvegicus with 6 samples.

How the data were processed

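Total RNA from PC12 cells, a line derived from a rat pheochromocytoma (a tumour of the adrenal medulla), was measured on 6 one-colour Agilent 4x44K rat arrays. Per the labels, cells were plated in dishes, given fresh medium with 0 or 1 ng/mL of nerve growth factor (NGF), and harvested after 6 h. The RNA was amplified and labelled with Cy3 with a low-input kit of the array maker. The titles number 3 control and 3 NGF samples. The labels do not say that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

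Each array file held the spot intensity written by Agilent Feature Extraction 9.5.1, per the submitters' processing notes, and the authors deposited these files without normalization between arrays. Per the file headers, the processed signal intensity had the spatial background surface subtracted and was detrended within the array. Each array carried 43379 non-control spots for 41012 probes, of which 263 probes were spotted more than once, up to 10 times. No spot was saturated on any array.

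The authors also deposited a table with the average of each group and the ratio of NGF to control for 28546 probes. That table holds linear values without per-array columns, so no test could be run on it. Its scale was found by setting it against the scanner values. When the log2 processed signals were quantile normalized, centred on each probe's median over the 6 arrays, taken as powers of e and averaged per group, the deposited averages were matched with a slope of 1 and a Pearson r of 0.9999 across probes in both groups. Taken as powers of 2, the slopes were 1.537 for control and 1.515 for NGF. A deposited ratio is therefore read here through its natural log, which stands on the log2 scale of the arrays. The column medians were 1.068 for control, 1.036 for NGF and 0.9632 for the ratio. The table held all 28492 probes that were well above background on at least 1 array and 54 others.

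The values analysed were log2 processed signals, averaged over repeated spots after spots marked as non-uniform were left out, minus the 75th percentile of each array over non-control probes. Probes were kept when they were well above background on at least 3 of the 6 arrays, whichever the group, which left 25469 probes. The brightest probe stood for each gene name, giving 21484 genes, of which 10592 had a gene symbol and the rest an accession number or probe ID. Of 21261 probes with a RefSeq accession, 16336 were found in a gene table of assembly GRCr8, which changed 3741 names. Other names are those of the array design. Coordinates are those of the probes in the rn4 build, per the file headers. Genomic sequence and exon annotation were not used here.

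NGF was compared with control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test, Benjamini-Hochberg adjustment over all genes, adjusted p below 0.05). Differences are NGF minus control in log2, with the standard error of the limma fit. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, over 21455 genes without a missing value, with Benjamini-Hochberg adjustment over the 20 lists. Camera with an estimated correlation and fry were run beside it. The groups, lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 largest rises and the 10 largest falls among called genes with a symbol whose groups did not overlap and that were well above background on all 3 arrays of the brighter group. It added 14 genes fixed by name, and the 3 members of each list with the smallest p. Where a called gene was not well above background on any array of a group, the fold is given as "at least": the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the lowest signal among that array's probes well above background and the probe's own signal. These bounds hold for the processed signal only: normexp background correction, which adds 50 to each signal, gives smaller differences for dim probes. Calls use the adjusted p before rounding.

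The fit was tested on simulated arrays, drawn from normal distributions with the means and limma's moderated variances of 21455 genes. With 3 arrays against 3 it recovered 6% of genes changed by 1 on the log2 scale, 72% of those changed by 2, 92% of those changed by 3 and 96% of those changed by 5, with 7 false calls among 140. The simulation changed 50 genes at each size and called 140, against 1110 called in the data, so its adjusted threshold was stricter. It drew each gene independently, without differences that many genes of an array share. The recovered shares therefore need not hold for the data. The small number of arrays limits the precision. Changes of 2-fold or less may be missed, and so may some larger ones, part of which the simulation also missed.

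All 3 control arrays lay on 1 slide with 1 scan, and all 3 NGF arrays on a second slide with a second scan, so slide and treatment cannot be told apart. Alternatives covered the background correction, the normalization, the filter, the choice of probe, the variance model, array weights, the replicate number as a block, and each array left out in turn. Scaling to 7 bright spike-in probes and a correction for the GC content of the probes were added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.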

Results

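The series measured gene expression in PC12 cells 6 h after 1 ng/mL NGF (3 arrays) against cells in medium with 0 ng/mL (3 arrays). PC12 cells stop dividing and grow neurites when kept in NGF, and the comparison asks which transcripts differ early in that programme. The 75th percentile of processed signal was 302.9, 794.3 and 986.6 on control arrays 1, 2 and 3, and 567.2, 597.5 and 486.6 on NGF arrays 1, 2 and 3. Between 57.12% and 64.02% of spots were well above background. Control array 1 was the dimmest, and its spike-in probes lay 3.97 above its 75th percentile on the log2 scale, against 2.98 to 3.58 on the other arrays. Control arrays 2 and 3 were the most alike (Pearson r across genes 0.9934), with a spread of 0.184 on the log2 scale over all genes tested. Control array 1 correlated better with NGF array 2 (0.9702) than with control array 2 (0.954) or control array 3 (0.9519). Repeated spots within an array had a median SD of 0.046 to 0.073. Those spots were all well above background and came from 153 to 170 probes per array, so the 2 spreads are not directly comparable.

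**Figure D1:**
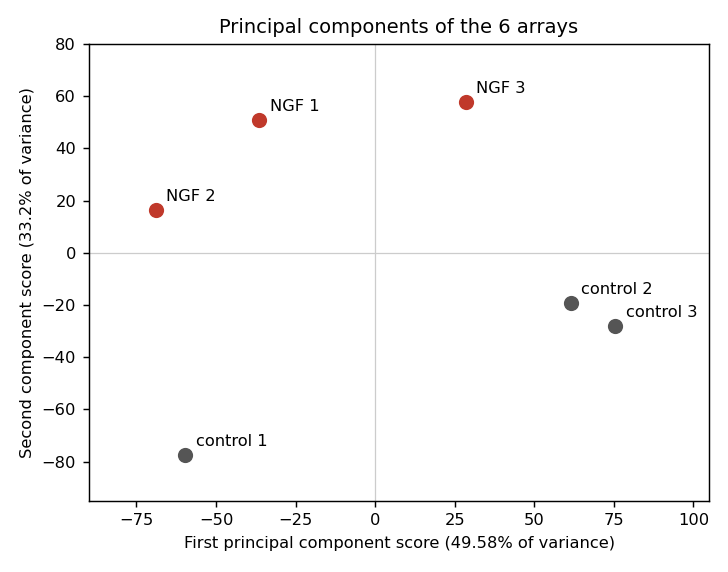
Scores of the 6 arrays on the first 2 principal components of 21455 genes, with control arrays in grey and NGF arrays in red. The first component (49.58% of the variance) sets control array 1 and NGF arrays 1 and 2 apart from the other 3 arrays, and the second (33.2%) separates the 2 groups.

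Transcripts of secreted matrix proteases, neuropeptide precursors, several immediate early transcription factors and feedback inhibitors of ERK signalling were higher with NGF. Those of DNA replication genes were lower. Each group lay on its own slide, so a slide difference cannot be told apart from NGF as the cause. As lists, neuropeptides with granins and processing enzymes, and immediate early factors, did not pass camera with an estimated correlation (adjusted p = 0.0828 and 0.161), and the other 3 did (0.0254, 0.0254 and 0.0112). The protease Mmp10 (stromelysin 2) was at least 311-fold higher and Mmp3 (stromelysin 1) at least 176-fold higher, with the control arrays not well above background. These bounds hold for the processed signal, and with normexp background correction the log2 differences were 6.13 and 5.37. The transcription factor Egr1 rose 42.2-fold (5.40 ± 0.27 SE on the log2 scale, n = 3 per group, limma adjusted p = 0.000473), and Dusp6, a phosphatase that inactivates ERK, rose 14.8-fold (3.89 ± 0.19, adjusted p = 0.000473). Under the alternatives run, the log2 differences of Egr1 and Dusp6 were as small as 4.27 and 3.65. Among falling genes, the origin recognition subunit Orc1 decreased by 2.17 ± 0.21 on the log2 scale (adjusted p = 0.00488). In every called gene named here, all 3 NGF arrays lay on the same side of all 3 control arrays. For the largest rises and falls, which include Mmp3, Mmp10 and Orc1, the naming rule required this, so it adds no evidence for them.

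Of 21484 genes tested, 604 were higher and 506 lower with NGF at adjusted p below 0.05 (limma). A change of at least 2-fold was shown by 547 of the higher and 396 of the lower genes, and 377 and 278 had a gene symbol. The groups did not overlap in 27.2% of genes. The 10% expected by chance is only the average over all splits of the arrays into 3 and 3. Many genes of an array share differences, so a given split can lie far from that average. The 27.2% therefore cannot tell a group difference from chance. The control group was not well above background on any array for 119 of the higher genes, and the NGF group for 14 of the lower genes. With spike-in scaling in place of the 75th percentile, 283 genes were higher and 31 lower. The counts were 819 and 535 without control array 1, 235 and 74 without control array 2, 221 and 51 without control array 3, 207 and 59 without NGF array 1, 274 and 112 without NGF array 2, and 288 and 133 without NGF array 3. Slide and treatment cannot be told apart.

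The 10 largest rises also held the collagenase Mmp13, which rose by 8.79 ± 0.26 on the log2 scale (adjusted p = 0.000155) and was well above background on 2 of 3 control arrays, and Gal, encoding the neuropeptide galanin, which rose by 7.97 ± 0.25 (adjusted p = 0.000155) and was well above background on 1 of 3 control arrays. For 8 of the 10 genes no control array was well above background, so their order is not given. Slc17a6, the vesicular glutamate transporter VGLUT2, was at least 117-fold higher (adjusted p = 7.99e-05). The serine protease gene Prss22 was at least 83.7-fold higher and Pnoc, encoding prepronociceptin, at least 71.5-fold higher. Stfa2l1, of the stefin family of cysteine protease inhibitors, was at least 68.0-fold higher, Crisp3, encoding a cysteine-rich secretory protein, at least 54.1-fold, and the cytochrome P450 gene Cyp3a9 at least 46.3-fold (limma adjusted p from 0.000226 to 0.000675 for these 5 genes). Each of the 10 kept its call without any 1 array. Over the alternatives run, the smallest log2 differences were 6.46 for Mmp13 and 5.68 for Gal. With normexp background correction the 8 genes differed by 3.64 to 6.13 on the log2 scale, less than their bounds, and were still called. Mmp3, Mmp10, Stfa2l1 and Cyp3a9 belong to families of similar sequence, and binding of a relative's RNA to the same probe was not excluded. The probes for Mmp13, Mmp3 and Mmp10 lay on chromosome 8 of rn4, with starts at 4168554, 4325061 and 4373403 and ends at 4168613, 4325526 and 4374134.

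The falls were smaller. Il17re, an interleukin 17 receptor family member, decreased by 2.73 ± 0.31 (adjusted p = 0.00765), the chemokine receptor gene Cxcr4 by 2.54 ± 0.22 (adjusted p = 0.00295) and the histamine receptor gene Hrh3 by 2.41 ± 0.34 (adjusted p = 0.0151) on the log2 scale. Hrk, which encodes a BH3-only promoter of apoptosis, decreased by 2.34 ± 0.20 (adjusted p = 0.00288). Dtl, a subunit of a ubiquitin ligase that acts in replication, decreased by 2.27 ± 0.27 (adjusted p = 0.00895). Cyp2c13 and Fam228a were at least 1.84-fold and 3.50-fold lower, with no NGF array well above background (adjusted p = 0.00688 and 0.00449), and Cyp2c13 belongs to a family of similar sequence. With normexp background correction neither was called, with differences of -0.51 and -0.61 (adjusted p = 0.503 and 0.215). The other falls also shrank under some alternatives, to -1.01 for Cxcr4, -1.46 for Il17re, -1.42 for Hrh3 and -1.42 for Dtl at the least. For Hrk and Cdc6 the smallest differences were -1.91 and -1.89. Without NGF array 1 the adjusted p of Il17re was 0.0504. Hrh3 lost its call without control array 2 or 3 or NGF array 1 or 2 (adjusted p up to 0.076), Dtl without control array 2 or 3 or NGF array 1 (up to 0.0621), and Cdc6, a replication licensing factor that decreased by 2.37 ± 0.38 (adjusted p = 0.0224), without any 1 array other than control array 1 (up to 0.106).

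**Figure D2:**
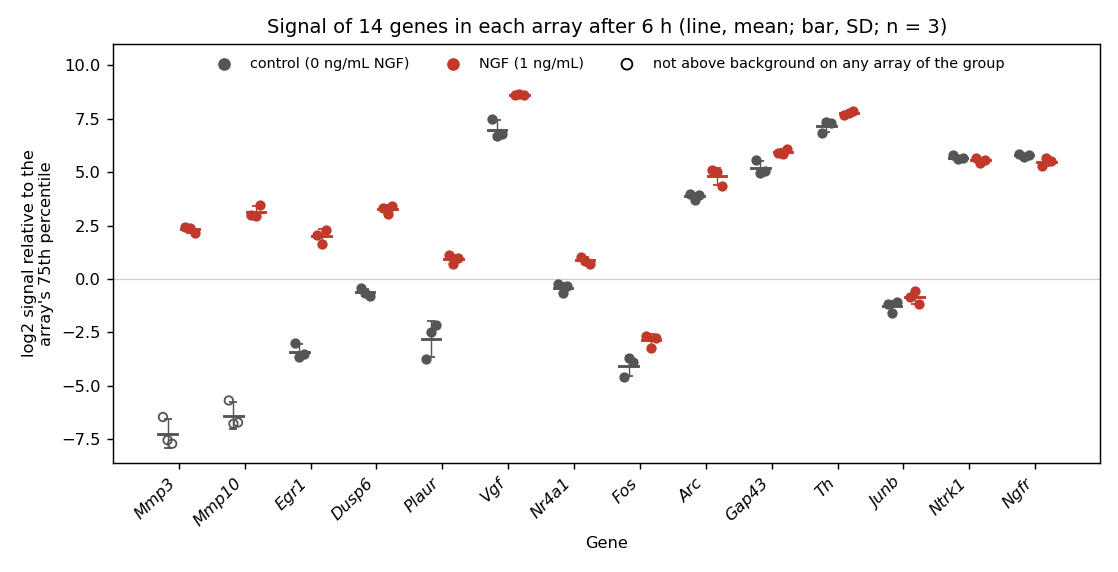
Signal on each array for 14 genes fixed by name, as log2 processed signal relative to the array's 75th percentile, after 6 h with 0 ng/mL (grey) or 1 ng/mL NGF (red). Lines are means and bars SD of 3 arrays, open circles mark a group with no array well above background, and levels are compared within a gene only. Mmp3, Mmp10, Egr1, Dusp6, Plaur, Vgf and Nr4a1 passed the test, and Fos, Arc, Gap43, Th, Junb, Ntrk1 and Ngfr did not.

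Among genes fixed by name, Plaur, the urokinase receptor, rose 13.2-fold (3.72 ± 0.43 on the log2 scale, adjusted p = 0.00765), Vgf, encoding a secreted peptide precursor, 3.10-fold (1.63 ± 0.25, adjusted p = 0.019) and the orphan nuclear receptor gene Nr4a1 2.42-fold (1.28 ± 0.19, adjusted p = 0.0189). Plaur lost its call without NGF array 1 (adjusted p = 0.0587), and Vgf and Nr4a1 lost theirs without any 1 array other than control array 1 (up to 0.101 and 0.0959). Fos differed by 1.18 ± 0.29 (adjusted p = 0.0803), Arc by 0.94 ± 0.25 (0.0954), Gap43, a growth cone protein gene, by 0.77 ± 0.22 (0.114), Th, the rate-limiting enzyme of catecholamine synthesis, by 0.59 ± 0.20 (0.173) and Junb by 0.44 ± 0.24 (0.381). The NGF receptor gene Ntrk1 differed by -0.12 (95% interval -0.52 to 0.28, adjusted p = 0.778), and Ngfr by -0.31 (-0.74 to 0.12, adjusted p = 0.419).

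**Figure D3:**
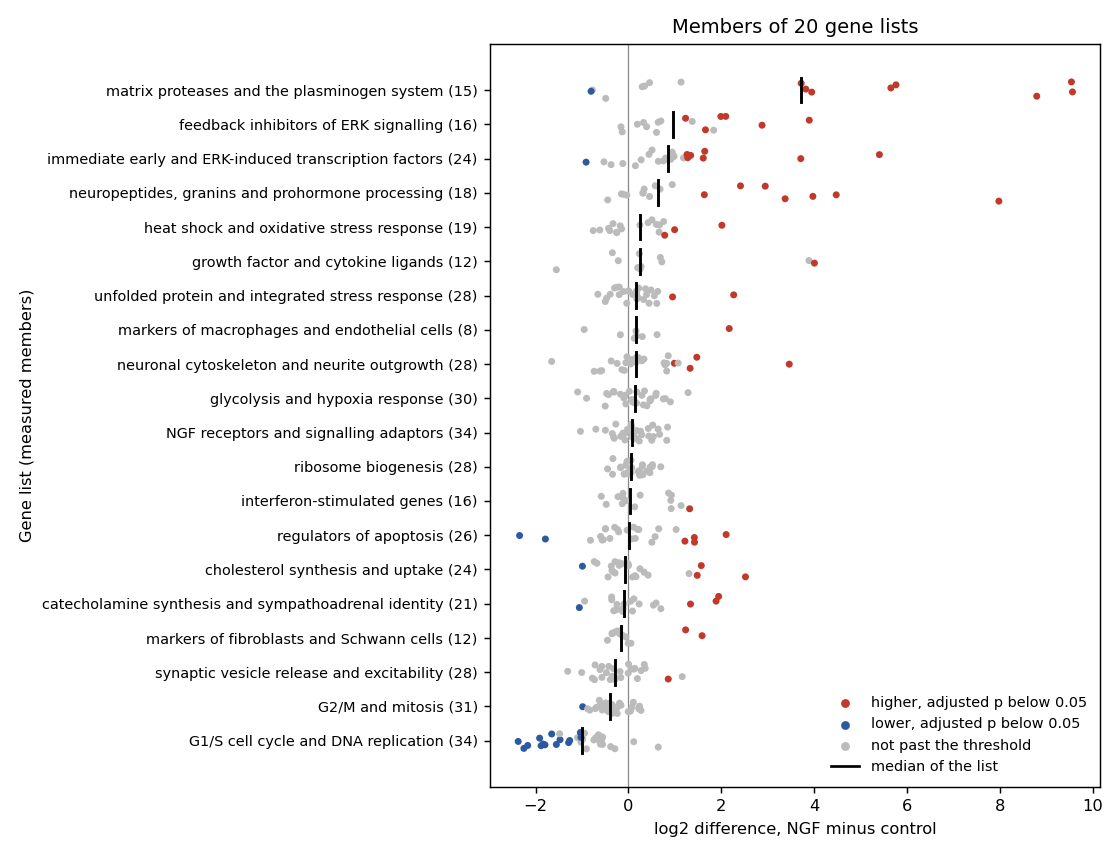
Difference between NGF and control (log2) for each measured member of 20 gene lists, with members called higher in red, called lower in blue and others in grey, the list median as a black line and the number of measured members in brackets. Medians run from -1.01 for G1/S genes to 3.72 for matrix proteases (0.91 with normexp background correction), and 14 of 34 G1/S genes were called lower.

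Of 15 measured genes for matrix proteases and the plasminogen system, 8 rose and 1 fell (10 and 2 adjusted over the list alone), the 1 that fell being Adam8 (decreased by 0.81 ± 0.16 on the log2 scale), which lost its call without any 1 array other than control array 1 (adjusted p up to 0.207). The list stood above other genes (camera adjusted p = 1.34e-08, and 0.0254 with an estimated correlation). Its median difference was 3.72, and 1.85 with the 5 members that had 1 group below background set to their bounds. It was 0.91 with normexp background correction and 0.69 over 20 members with no filter on dim probes. With probes well above background on all 6 arrays, only 8 members were left, 1 rose and 1 fell, and camera gave an adjusted p of 0.526.

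Immediate early and ERK-induced transcription factors stood above other genes as a list only with the preset correlation (camera adjusted p = 2.43e-07, and adjusted p = 0.161 with an estimated correlation). Of 24 measured members 7 were higher and 1 was lower (10 and 1 adjusted over the list alone). Besides Egr1, Fosl1, which encodes the AP-1 subunit Fra-1, rose 13.1-fold (3.71 ± 0.28, adjusted p = 0.00214) and Ier3 2.40-fold (1.26 ± 0.18, adjusted p = 0.0159). The 1 lower member was Srf, which decreased by 0.91 ± 0.18 (adjusted p = 0.0401). Ier3 and Srf lost their calls without any 1 array other than control array 1 (adjusted p up to 0.0965 and 0.2). Each of those 5 fits called 2 members higher, as did spike-in scaling and the replicate number as a block. With no filter on dim probes, 2 of 28 members were higher.

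Feedback inhibitors of ERK signalling rose, with 6 of 16 measured members higher and 0 lower (9 and 0 adjusted over the list alone; camera adjusted p = 9.31e-08, and adjusted p = 0.0254 with an estimated correlation). Beside Dusp6, the adaptor gene Sh2b3 rose 7.33-fold (2.87 ± 0.25, adjusted p = 0.00297) and Errfi1, an inhibitor of the EGF receptor, 4.27-fold (2.09 ± 0.22, adjusted p = 0.00596). These 3 kept their calls without any 1 array, while the list count was 3 without control array 2, control array 3 or NGF array 1, and 4 without NGF array 2 or 3.

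In the list of neuropeptides, granins and prohormone processing genes, 7 of 18 measured members were higher and 0 lower (9 and 0 adjusted over the list alone; camera adjusted p = 9.2e-08, and adjusted p = 0.0828 with an estimated correlation). All 7 encode peptide precursors, and no chromogranin, secretogranin or processing gene of the list was called over all genes. Vip, encoding vasoactive intestinal peptide, was at least 10.4-fold higher (adjusted p = 0.000816) and Crh, encoding corticotropin-releasing hormone, at least 4.55-fold (adjusted p = 0.00131), with the control arrays not well above background. The median difference of the list was 0.63, and 0.34 with no filter on dim probes, where 5 of 23 members were higher. Its count was 3 without control array 2 or NGF array 1, and 4 without control array 3, NGF array 2 or NGF array 3. With normexp background correction it was 3, Crh was not called (1.06 on the log2 scale, adjusted p = 0.167) and Vip differed by 1.58, and 1 of 12 members passed when probes had to be well above background on all 6 arrays.

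Genes of the neuronal cytoskeleton and neurite outgrowth passed more weakly. Of 28 measured members 4 rose and 0 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0366, and adjusted p = 0.314 with an estimated correlation). The 4 were the kinase gene Dclk1 (3.46 ± 0.22 on the log2 scale, adjusted p = 0.00132), the neurofilament genes Nefl (2.77-fold, 1.47 ± 0.18, 0.00936) and Nefm (2.51-fold, 1.33 ± 0.18, 0.0145), and Basp1 (0.99 ± 0.18, 0.0367). The list lost its call without control array 1 (adjusted p = 0.106), control array 2 (0.0531), NGF array 2 (0.0999) or NGF array 3 (0.0813), with array weights (0.152), with the replicate number as a block (0.079) and with spike-in scaling (0.084). Nefl was not called without control array 2 or 3 or NGF array 1 (adjusted p up to 0.0669), nor Nefm and Basp1 without any 1 array other than control array 1 (up to 0.0864 and 0.184). Basp1 and members of other lists that fall outside the fixed rule, such as Adam8 and Srf, are named because their counts were small, after their values were seen.

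G1/S cell cycle and DNA replication genes fell. Of 34 measured members 14 were lower and 0 higher (26 and 1 adjusted over the list alone), and 32 had a negative difference. The median difference was -1.01, and the list stood below other genes (camera adjusted p = 6.11e-17, and 0.0112 with an estimated correlation). The repressor E2f8 decreased by 2.25 ± 0.22 (adjusted p = 0.00492) and Mcm10, a replication initiation factor, by 1.80 ± 0.19 (adjusted p = 0.00563) on the log2 scale. The smallest differences among the alternatives run were -1.11 for E2f8, -1.42 for Mcm10 and -1.91 for Orc1. Orc1, E2f8 and Mcm10 kept their calls without any 1 array, but Orc1 and Mcm10 lost theirs with the replicate number as a block (adjusted p = 0.0545 and 0.0539), and Mcm10 with spike-in scaling (0.102). The list's count of lower genes was 4 without control array 2, control array 3, NGF array 1 or NGF array 2, 5 without NGF array 3, 2 with spike-in scaling, 1 with the replicate number as a block and 26 with array weights. Its camera adjusted p was 4.71e-15 or less in each of these.

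G2/M and mitosis genes stood below other genes as a list only with the preset correlation. Of 31 measured members 1 was lower and 0 higher (3 and 0 adjusted over the list alone), with a median difference of -0.39 (camera adjusted p = 0.000112, and adjusted p = 0.0621 with an estimated correlation). The 1 lower gene was Birc5, encoding survivin, which decreased by 0.99 ± 0.18 on the log2 scale (adjusted p = 0.0353) and lost its call without each single array (adjusted p from 0.0504 to 0.174). Ccna2, encoding cyclin A2, differed by -0.71 ± 0.16 (adjusted p = 0.0579).

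The other 13 lists did not pass the camera test, and no direction is given for them. Among them, fry passed interferon-stimulated genes (adjusted p = 0.0113), heat shock and oxidative stress (0.0113) and the unfolded protein and integrated stress response (0.0298). It also passed growth factor and cytokine ligands (0.0301) and ribosome biogenesis (0.0393). Fry does not ask whether a list stands apart from other genes. Of 21 genes for catecholamine synthesis and sympathoadrenal identity, 3 rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.641), with a median of -0.10 and a mean of 0.16. Gch1, which encodes an enzyme in the synthesis of the cofactor of tyrosine hydroxylase, rose 3.84-fold (1.94 ± 0.16, adjusted p = 0.00283). The homeodomain gene Isl1 rose 3.69-fold (adjusted p = 0.00564) and the receptor kinase gene Ret 2.52-fold (adjusted p = 0.0131). The nicotinic receptor gene Chrna3 decreased by 1.06 ± 0.21 on the log2 scale. Ret lost its call without any 1 array other than control array 1 (adjusted p up to 0.0766), and Chrna3 without each single array (0.0535 to 0.2). Of 26 regulators of apoptosis 4 rose and 2 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.993). The 2 that fell were Hrk and Birc3, an inhibitor of apoptosis that was at least 2.73-fold lower, and the 4 that rose were Tnfrsf12a (4.29-fold), Bid (2.67-fold), Mcl1 (1.21 on the log2 scale) and Cflar (1.42). Bid lost its call without control array 2 or 3 or NGF array 1 or 2 (adjusted p up to 0.0728), Mcl1 and Cflar without any 1 array other than control array 1 (up to 0.11 and 0.162), and Birc3 without any other than NGF array 3 (up to 0.132). Birc3 was also not called with normexp background correction or with quantile normalization.

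Of 24 cholesterol genes 3 rose and 1 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.993), with a median of -0.08 and a mean of 0.14. The LDL receptor gene Ldlr was at least 3.34-fold higher, Hsd17b7 rose 2.96-fold and Msmo1 2.79-fold, and Dhcr7 decreased by 0.99 on the log2 scale. Of 28 genes of the unfolded protein and integrated stress response 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.26), Slc7a11, a cystine transporter gene, at least 2.88-fold and Edem1 1.93-fold. Of 19 heat shock and oxidative stress genes 3 rose and 0 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.199), Srxn1 4.03-fold, the co-chaperone gene Bag3 1.99-fold and Hmox1, heme oxygenase 1, 1.72-fold, just under the threshold. Dhcr7, Edem1 and Hmox1 lost their calls without each single array (adjusted p up to 0.195, 0.202 and 0.207), and Msmo1 and Bag3 without any 1 other than control array 1 (up to 0.0925 and 0.163). Ldlr was not called without control array 3 or NGF array 1 or 2 (up to 0.0725), Hsd17b7 without control array 2 or NGF array 1 (up to 0.0647), nor Slc7a11 without control array 2 or 3 or NGF array 1 or 3 (up to 0.0726). With normexp background correction Ldlr and Slc7a11 were not called (adjusted p = 0.391 and 0.456).

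Of 28 genes for synaptic vesicle release and excitability 1 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.178). It was Unc13a (0.86 ± 0.17, adjusted p = 0.0466), which lost its call without each single array (0.0607 to 0.214). Of 12 growth factor and cytokine ligands 1 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.178, and 0.0499 with spike-in scaling), the chemokine gene Ccl2, at least 4.07-fold higher (adjusted p = 0.00449), which was not called with normexp background correction (1.03 on the log2 scale, adjusted p = 0.206). Of 16 interferon-stimulated genes 1 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.178), Gbp2, which lost its call without any 1 array other than control array 1 (up to 0.179). None of 34 NGF receptor and adaptor genes, 30 glycolysis and hypoxia genes and 28 ribosome biogenesis genes passed limma's adjusted threshold, over all genes or adjusted over the list alone, and their camera adjusted p were 0.717, 0.334 and 0.339.

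Markers of other cell types did not pass as lists. Of 12 markers of fibroblasts and Schwann cells 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.993), with a median of -0.16 and a mean of 0.07. The 2 were the collagen gene Col6a1 (1.58 ± 0.18 on the log2 scale, adjusted p = 0.00756) and the myelin gene Pmp22 (1.23 ± 0.18, adjusted p = 0.0163). Of 8 markers of macrophages and endothelial cells 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.26), Eng, encoding endoglin, at least 2.59-fold higher (adjusted p = 0.0118). Col6a1 lost its call without control array 2 (adjusted p = 0.0512), Eng without control array 3 or NGF array 1 or 3 (up to 0.0687), and Pmp22 without any 1 array other than control array 1 (up to 0.0952). With normexp background correction none of the 3 was called (adjusted p = 0.13, 0.387 and 0.193 for Col6a1, Eng and Pmp22), nor with the replicate number as a block (0.074, 0.0914 and 0.104). Col6a1 and Pmp22 were not called with spike-in scaling (0.132 and 0.273), Eng with quantile normalization (0.0728) or the plain two-sample test (0.0513), nor Pmp22 without the filter on dim probes (0.0647).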

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

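Spike-in scaling and the correction for probe GC content were chosen after the data were seen, as was the family test with no filter on dim probes, which left 1 of 5 gene families past the threshold. The counts of 604 higher and 506 lower genes became 316 and 257 with normexp background correction, 316 and 141 with no filter on dim probes, 2179 and 1924 with array weights, 283 and 31 with spike-in scaling, and 234 and 74 at adjusted p below 0.01. The cause was not tested, except that the last follows from the stricter threshold. Leaving out each array in turn gave 207 to 819 higher and 51 to 535 lower genes. Each fit had fewer arrays, but without control array 1 more genes were called. Under the other alternatives run (quantile normalization, median centring, probes above background on all 6 arrays, the median over probes, every probe, the intensity trend with robust moderation, the plain two-sample test, the GC correction and a change of at least 2-fold) both counts stayed within 1.5 times. No called gene was called in the opposite direction under any of them. Spike-in scaling moved the median of all genes from 0.04 to 0.16 on the log2 scale, and 90.1% of its calls were higher against 54.4%. With the replicate number as a block, 180 genes were higher and 31 lower. The residual correlations of arrays with the same number were 0.035, -0.578 and 0.647, and control arrays 1 and 2 correlated best with NGF arrays 2 and 3, so the numbers were not taken to pair the samples. The cause of the lower block counts was not tested. A block for slide or scan could not be run, because each slide held 1 group. Of 20 lists, 7 passed camera, 3 with an estimated correlation and 12 with fry, which asks only whether a list's genes move on balance one way. The other list fits passed 6 or 7, and lists were not run with every probe or the plain two-sample test. The cause was not tested. Of 55 called genes named by the fixed rule, 30 kept the call without each array in turn and 25 lost it without at least 1. Among all 83, up to 25 lost their call (with the replicate block) and up to 21 gained 1 (with array weights) under a single alternative. Ntrk1, not called, changed sign with spike-in scaling (0.0064). The natural log of the ratio in the authors' deposited table stood within 1 SD of the fitted difference for all 83 named genes. That SD is the spread between replicates, pooled over the 2 groups. The deposited averages match the same 6 arrays and their scale was found from them, so this is not an independent check. Genes with a group below background have only a bound, which is what signal over background limits.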

Other observations

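The tests of gene families, of a slide difference, of probe GC content and of the G1/S list against the G2/M list were chosen after the result was seen. Several keratin, prolactin-family and kallikrein-related transcripts also rose with NGF, but as families they passed only among probes kept by the filter. Gene families were formed by symbol stem, among families with at least 4 measured members, and their share of called genes was compared with that of all 10081 genes with a symbol in the reference table by a one-sided Fisher's exact test, adjusted over all families and both directions. A gene that is bright only with NGF counts as measured because it rose, so the test was repeated with no filter on dim probes. Of 12 measured keratin genes 7 rose and 0 fell (adjusted p = 4.78e-05), and 4 of 32 without the filter (adjusted p = 0.173). The 7 include Krt7 (8.06-fold, 3.01 ± 0.17 on the log2 scale) and the simple-epithelium partners Krt8 (5.63-fold) and Krt18 (3.48-fold). The count was 2 without NGF array 1, 3 without control array 3, 4 without NGF array 2 or 3, and 4 with normexp background correction. Krt7 and Krt18 passed without each array in turn, and Krt8 did not without control array 3 or any 1 NGF array (adjusted p up to 0.127). Of 7 kallikrein-related peptidase genes 4 rose (adjusted p = 0.01), and 4 of 18 without the filter (adjusted p = 0.0507), with Klk6 at least 11.5-fold and Klk10 at least 3.12-fold higher, Klk7 4.74-fold and Klk8 2.84-fold, and 1 passed with normexp. Klk6 lost its call without NGF array 1 (adjusted p = 0.0591) and Klk8 without control array 3 (0.053).

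Of 6 measured genes of the prolactin family, whose members other than prolactin are known mainly from the rodent placenta, 4 rose (adjusted p = 0.00702), and 4 of 21 without the filter (adjusted p = 0.0641). Prl7a3 was at least 20.4-fold higher, Prl7d1 at least 5.57-fold, Prl6a1 at least 4.79-fold and Prl3b1 at least 3.58-fold, with no control array well above background, and all 4 passed without each array in turn. With normexp 1 passed. The members of these 3 families are similar in sequence and several are neighbours in the genome, so they are not independent, and binding of a relative's RNA to a probe was not excluded. Of 8 genes with the symbol stem Mcm, which are 7 minichromosome maintenance genes and Mcm3ap, an associated protein's gene, 4 were lower by the same test (adjusted p = 0.00702), and 1 without the filter (adjusted p = 1), and matrix metalloproteinase genes 6 of 15 higher and 1 lower (adjusted p = 0.00377), and 5 of 23 higher without the filter (adjusted p = 0.0134). The first count was 1 without control array 2, control array 3, NGF array 1 or NGF array 2, 2 without NGF array 3, and 0 with spike-in scaling, and the second was 4 or 5 higher without each array in turn. Both families are held in part by lists reported above.

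For all 83 genes named by the fixed rule, the ratio in the authors' deposited table lies farther from 1 than the fitted ratio of NGF to control, in both directions. Egr1 has a deposited ratio of 208, and 42.2-fold was fitted here. Dusp6 has 48.6 against 14.8-fold, and Nr4a1 has 3.57 against 2.42-fold. Among falling genes, Cdc6 has a deposited ratio of 0.0763 against a fitted ratio of 0.193, and Orc1 has 0.116 against 0.222. The deposited averages match powers of e taken of log2 values, with a slope of 1, and a count of genes past a fold threshold in that table uses a smaller fold on the arrays than the number states.

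For the number of genes called, the 6 arrays can be split into 3 and 3 in 10 ways, of which 2 call as many genes as NGF against control, too few ways for a share under 0.05. The real split called 1110 genes and the highest other 1909, setting control array 1 and NGF arrays 1 and 2 against the rest, while each of the other 8 called 0. That points to a structure of the samples beside the treatment. A slide or scan difference could also give calls between the groups: 0 slides held arrays of both groups, so it cannot be told apart from NGF.

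For that other structure, GC content of the probes is not the whole of it, since the split still called 1700 genes after the GC correction. If RNA integrity or labelling had acted probe by probe, 2 probes of the same gene would share little of the difference. Their correlation across 3200 genes was 0.441 (95% bootstrap interval 0.396 to 0.483), between the bounds of 0.3 and 0.5 set beforehand. An effect on probes may therefore account for part of this structure and stays open. If RNA integrity or labelling had acted on whole transcripts, 2 probes of a gene would share the effect, so the correlation cannot decide on that. The NGF difference gave 0.72, with called genes and their large differences included, so the 2 correlations are not like for like. The labels name no culture batch that the split follows, and no biological explanation was tested.

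The fall of the G1/S list was not a matter of signal-dependent bias: 0% of 10000 random lists matched on mean signal had a median as low, with 95% of their medians between -0.19 and 0.16 against -1.01. The uneven share of the 2 kinds of array (33.3% of control and 66.7% of NGF arrays are of the kind of control array 1) would carry -0.011 of it. A slide difference stays open, as for every result here, and so does the treatment. As a hypothesis, the G1/S list may have fallen further than the G2/M list. The mean of the first minus the mean of the second was 0.33 ± 0.06 (SD, n = 3) on control arrays and -0.41 ± 0.02 (SD, n = 3) on NGF arrays, a difference of -0.736, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow. The order would be consistent with cells leaving the G1/S programme before those already past it finish mitosis, which a single time point does not test.

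Another hypothesis was that genes higher with NGF lie beside each other in the genome. Among 10284 genes placed by their order in the reference gene table, 371 were higher, and 24 neighbouring pairs of different symbol stem were both higher. Random draws of as many genes gave 12.84 such pairs on average and 28 at most (one-sided permutation test with 10000 draws, p = 0.0025). Some of these pairs are still relatives, such as Nefl with Nefm, so shared sequence or shared origin may account for part of the excess of the 24 pairs, and regulation of neighbours was not tested.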
